A study of Mus musculus with 230 samples.

How the data were processed

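Single-cell RNA was measured in 121 E15 cells and 109 P2 cells, sorted as tdTomato-positive after tamoxifen. Per the labels, the authors demultiplexed reads with bcl2fastq 2.15.0.4, trimmed them with cutadapt 1.9.1, aligned them with STAR to GRCm38.p4 and counted them per gene with featureCounts; no versions are stated for the last tools. The deposited values are RPKM, in a table per age with 1 column per cell and the same 46983 gene names. The annotation, the counting options and the read total behind the RPKM are not stated. The unit was checked on the values: with gene lengths from the exon unions of GENCODE M21, available for 45646 of the names, the lowest values of a cell (up to 20 reads) should be whole multiples of 1 read. The median share of such values within 0.02 of a whole read was 81.4% in E15 cells and 79.2% in P2 cells. This step gave each cell's read total (median 6.50 M at E15 and 5.90 M at P2, M for mega) and the reads assigned to genes. 15 gene names had been turned into date-like forms and were left as they are. The libraries carry no strand, so overlapping genes on opposite strands cannot be told apart; 50 of the 134 named genes have exons that overlap another gene.

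Cells were grouped by age from the labels and by plate from the format of the cell titles, which is an inference. 1 P2 column with 0 for every gene was left out. A gene was detected in a cell at RPKM of at least 1, and measured when detected in at least 10% of the cells of either age. The level of a gene was the mean over cells of log2(RPKM + 1), and the difference was P2 minus E15, for all cells and for each of the 4 pairs of an E15 and a P2 plate. With 1 sample per age, no test was made and no count of changed genes is given. The precision of a share of cells is an exact (Clopper-Pearson) 95% binomial interval, and a count of 0 was read against a floor of 3 cells, which limits cells with the transcript detected and not cells that express it. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

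The 35 gene lists, the rule for named genes and the comparisons were fixed before the data were examined. For a list with at least 3 measured members, the median difference was set against 10000 random lists of the same size matched on mean level in 20 bins, and a percentile below 2.5 or above 97.5 counted as outside. This describes these libraries and is not a test between samples. Named genes were the 12 with the largest higher and the 12 with the largest lower levels among genes detected in at least 25% of the cells of either age, with a difference of at least 1 in that direction in every pair of plates. Predicted or clone-named models, Xist, Tsix and Y-linked genes were left out. From each list, up to 4 measured members with the largest absolute difference were added, and 15 genes were fixed by name for shares of cells. The share of cells with many G2/M genes, and Gad2 and Sparcl1 as shares, were added after the values were seen.

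Clusters came from Ward clustering of centred log2(RPKM + 1) over the cell type markers with RPKM of at least 1 in at least 5 cells (71 genes), with 6 clusters. A cluster was named when at least 3 of its top 10 genes came from 1 cell type list and no other list did so. Comparisons within a class needed 10 cells of each age and were not made, since no named class had them. Alternatives were a pseudocount of 0.1, the log2 of the mean RPKM, rescaling to a common total (TPM scale) or by the median ratio over 333 widely detected genes, and no filter on low values. Others left out cells with few detected genes, the 8 cells of E15 set B with title numbers from 62 to 69, or each plate in turn. Cells of E15 set A with such numbers were kept. Cells were also matched on detected genes within 10%, or left out above 20% mitochondrially encoded RPKM. Other detection limits were above 0 and at least 5 RPKM. Clustering was repeated with 5 or 8 clusters, on 1500 variable genes with 20 principal components, on each age alone and on the TPM scale. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The steps were tested on simulated data made from E15 cells split at random. There, 80% of genes raised 16-fold and 26% raised 4-fold had a difference of at least 1 in every pair of plates. The same held for 50% of genes lowered 16-fold, 6% lowered 4-fold and 0.028% of unchanged genes. In this simulation the rule for named genes thus missed many changes, and lower ones more often. A random split holds no systematic difference between plates or sexes, so the 0.028% is not an error rate for these data.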

Results

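Gene expression was measured in single cells that carried the red reporter tdTomato after tamoxifen had switched on a recombinase driven by regulatory sequences of Neurog2, a proneural transcription factor of glutamatergic progenitors. Cells came from C57BL/6 mice 12 h after tamoxifen, either from the pallium at embryonic day 15 (E15) or from the dorsal subventricular zone at postnatal day 2 (P2). The cells were captured on microfluidic chips, and each one gave its own library of 75 bp single reads at a stated depth of 7 M reads (M, mega). The tables hold 230 cells, 121 at E15 and 109 at P2. The cell titles fall into 2 groups per age, called plates here: E15 set A (60 cells), E15 set B (61 cells), P2 plate 1 (56 cells) and P2 plate 2 (53 cells). 1 column of P2 plate 1 is 0 for every gene and was left out, so 229 cells were compared. The labels name no animal or litter, so each age counts as 1 sample and cells are not replicates. No test, p-value or standard error is therefore given, and the spread beside each difference is its range over the 4 pairs of an E15 and a P2 plate. Age and dissected region differ together in this design, and transcripts that depend on the sex of the animals differed between the ages too, as given below.

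At E15 a cell had a median of 2867 detected genes (RPKM of at least 1, that is, reads per kilobase of gene and M reads), with a range from 809 to 4329. P2 cells had a median of 2025 and at most 3339. The difference was -842 genes and ranged from -1079 to -592.5 over the pairs of plates. Reads assigned to genes, estimated from the step size of the lowest values in each cell, had a median of 3.19 M at E15 (0.791 to 6.55 M). At P2 the median was 2.79 M (0.114 to 5.57 M). Mitochondrially encoded transcripts took a median of 9.13% of the RPKM total at E15 and 7.58% at P2, and 22 E15 cells and 2 P2 cells were above 20%. Fewer than 50% of the median number of genes of their age were detected in 13 E15 cells, 11 of them in set A, and in 3 P2 cells.

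**Figure D1:**
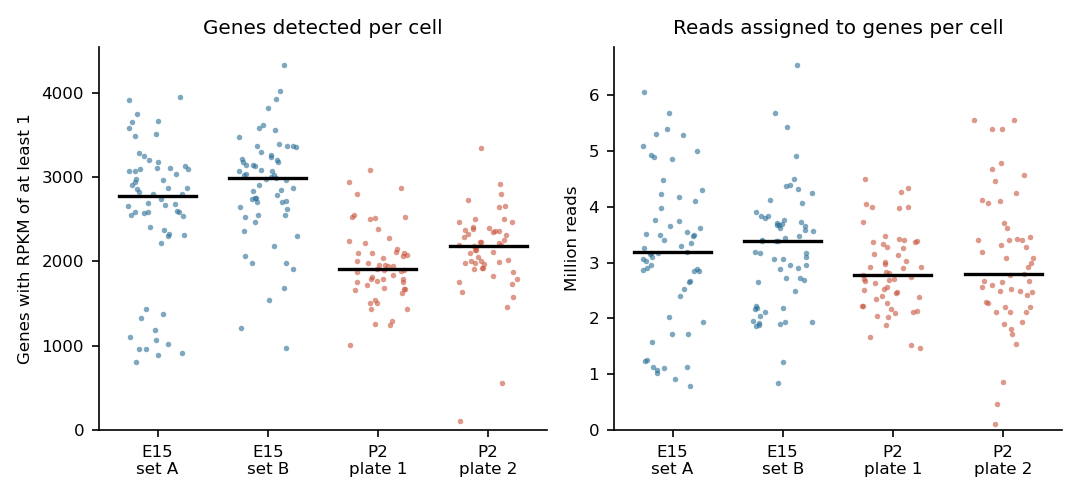
Genes detected per cell at RPKM of at least 1 (left) and reads assigned to genes per cell, in M (right) for the 4 plates; each point is a cell and each line the median of its plate. Medians of detected genes were 2771.5 and 2988 in the E15 plates and 1909 and 2179 in the P2 plates.

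The comparison of P2 with E15 asks how glutamatergic progenitors and the young neurons they give differ before and after birth. Of the 12 genes with the largest higher levels at P2, Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, came at the top. It had a mean of 3.21 RPKM at E15 and 77.7 at P2, a 24.2-fold ratio, and was detected in 24.8% of E15 cells and 78.7% of P2 cells. Sema3c, a secreted semaphorin, had means of 18.0 and 110 RPKM and was detected in 47.1% and 89.8% of cells. Cdk6, a cyclin D-dependent kinase, had means of 11.3 and 62.4 RPKM.

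In mean log2(RPKM + 1), P2 minus E15, the difference was 3.83 for Spry2 (3.32 to 4.35 over the pairs of plates), 3.62 for Sema3c (3.15 to 4.10) and 3.28 for Cdk6 (2.96 to 3.60). The POU-domain factors Pou3f2 and Pou3f3, known from upper layer neurons, were higher by 2.95 (1.53 to 4.40) and 2.26 (1.85 to 2.68). Pou3f2 was detected in 78.5% of E15 cells and 98.1% of P2 cells, at means of 84.5 and 318 RPKM. Its difference was 1.83 without E15 set A, and it also shrank by over 1.5 times with the log2 of the mean RPKM. Egr1, an immediate early transcription factor, was higher by 2.67 (2.42 to 2.93) and was detected in 8.26% of E15 cells and 59.3% of P2 cells. Zbtb20, a zinc finger repressor, was higher by 2.10 (1.69 to 2.52), with detection in 66.1% and 97.2% of cells. Fam84a (3.03, and 1.95 with the log2 of the mean RPKM), Kdelr2 (2.18), Sod1 (2.17), Lyrm4 (2.12) and Pam (2.09) complete the 12 genes of the naming rule. Kdelr2 returns resident proteins to the endoplasmic reticulum, and Sod1 is the cytosolic superoxide dismutase. Sod1 had a mean of 195 RPKM at E15 and 555 at P2, and its difference was 1.21 without cells above 20% mitochondrially encoded RPKM.

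Of the 12 genes with the largest lower levels at P2, Nrp1, a receptor for secreted semaphorins, came at the top. It had a mean of 72.4 RPKM at E15 and 12.4 at P2, and was detected in 91.7% and 27.8% of cells. Its difference in mean log2(RPKM + 1) was -4.03 (-4.49 to -3.57 over the pairs of plates). Map1b, a microtubule-associated protein, followed at -3.64 (-4.02 to -3.26), with means of 236 and 45.3 RPKM. Epha3, an ephrin receptor, was at -3.46 (-4.37 to -2.54). The neuronal differentiation factors Neurod6 and Neurod1 were at -3.32 (-3.67 to -2.97) and -3.01 (-3.36 to -2.65). Neurod6 stayed a highly expressed gene at P2, with a mean of 202 RPKM against 741 at E15.

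Cdkn1c, an inhibitor of cyclin-dependent kinases, was at -3.17 (-3.43 to -2.91) and was detected in 62.0% of E15 cells and 4.63% of P2 cells. Tiam2, an activator of the GTPase Rac, was at -2.85, with detection in 64.5% and 1.85% of cells. Sema6d, a transmembrane semaphorin, was at -2.66, with detection in 71.9% and 3.70% of cells. Dusp14, a phosphatase, had a mean of 44.4 RPKM and was detected in 51.2% of E15 cells, while no P2 cell reached 1 RPKM. Its difference was -2.78, and no fold is given against a group at that level. Flrt1 (-2.84), Abracl (-2.75) and Fam114a2 (-2.59) complete this group of 12. With the log2 of the mean RPKM, differences of the lower genes shrank by over 1.5 times for Nrp1 (-2.45), Map1b (-2.35), Neurod6 (-1.87), Neurod1 (-1.55), Abracl (-1.74) and Fam114a2 (-1.42). Abracl was at -1.43 in cells matched on detected genes. Of all 24 genes, 8 had differences over 1.5 times larger with a pseudocount of 0.1. On the TPM scale 7 of these genes did so too, where a pseudocount of 1 also weighs less.

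The median difference over the 7493 measured genes was -0.24, and the middle 90% lay between -1.02 and 0.40. On the TPM scale this median was -0.38. That scale raises every value, since the RPKM totals had medians of 119276 at E15 and 114075 at P2. A pseudocount of 1 then weighs less, and 9248 genes counted as measured, so this shift is not one of scaling alone. Rescaling by the median ratio gave -0.20. Each list was read against random lists of genes with similar levels and not against 0. The difference kept its sign in every pair of plates for 59.4% of the measured genes. The 33.3% expected by chance holds only without a shift common to most genes. The median of -0.24 was not removed, so how far that shift accounts for the excess was not measured. Plates differed too: the standard deviation over genes was 0.475 between the ages, 0.378 between the E15 plates and 0.345 between the P2 plates. Both ages are in separate tables, with the same 46983 gene names. The libraries carry no strand, and exons of 9 of the 24 genes above overlap another annotated gene: Cdk6, Lyrm4, Zbtb20, Pam, Nrp1, Cdkn1c, Neurod1, Tiam2 and Abracl. On GRCm38, Spry2 lies on chromosome 14 from 105891947 to 105896819 on the minus strand and Sema3c on chromosome 5 from 17574281 to 17730268 on the plus strand. Nrp1 lies on chromosome 8 from 128358604 to 128503363 on the plus strand. Neurod6 lies on chromosome 6 from 55677822 to 55681263 on the minus strand.

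**Figure D2:**
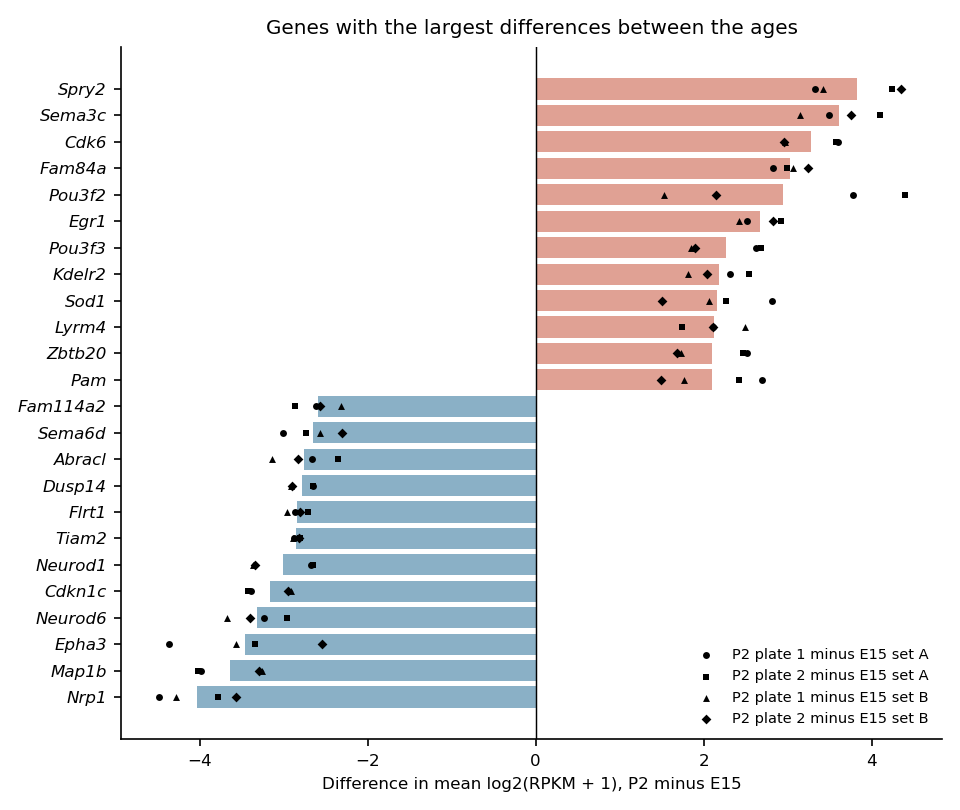
Difference in mean log2(RPKM + 1), P2 minus E15, for the 12 genes with the largest higher and the 12 with the largest lower levels; bars are all cells and markers the 4 pairs of plates. Bars run from -4.03 for Nrp1 to 3.83 for Spry2, and every pair of plates has the sign of its bar, as the naming rule requires.

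Markers of glutamatergic neurons were lower at P2 as a group. Of the 13 measured members, 12 were lower and 1 was higher in every pair of plates, 10 of them lower by at least 1 log2 unit in every pair. The median difference was -1.97 (-2.23 to -1.89 over the pairs of plates), and none of 10000 random lists matched on mean level was as low (percentile 0). Besides Nrp1, Neurod6 and Neurod1, the zinc finger factor Bcl11a was at -2.48 and was detected in 94.2% of E15 cells and 56.5% of P2 cells. Neurod2 was at -2.23, while Tbr1 was at -0.13 and turned to 0.26 with the log2 of the mean RPKM. Fewer genes were detected per P2 cell, as given above, and this holds beside every list that was lower.

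Genes of deep layer neurons were lower at P2 and genes of upper layer neurons higher. All 6 measured deep layer genes were lower in every pair of plates, with a median of -1.13 (-1.18 to -0.96, percentile 0.02). Of these, Bcl11b, Fezf2, Sox5 and Tbr1 are also in the glutamatergic list, so the lists are not independent; the remaining 2 genes were at -0.80 and -0.23. Bcl11b, a factor of subcerebral projection neurons, was at -2.42 and was detected in 71.9% of E15 cells and 8.33% of P2 cells. Sox5 was at -1.87, with detection in 78.5% and 24.1% of cells, and Fezf2 at -1.45, with 38.0% and 1.85%. Without a filter on low values the deep layer percentile was 26.97. Of 8 measured upper layer genes, 5 were higher and 1 was lower in every pair, with a median of 0.68 (0.18 to 1.19, percentile 99.98). The upper layer list shares 2 measured genes with the glutamatergic list. Pou3f2 and Pou3f3 led it, whereas Lhx2 was at -1.45, with a wide range from -3.11 to 0.25.

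Among progenitor markers, genes of intermediate progenitors were lower and a few of radial glia higher. Of 13 measured intermediate progenitor genes, 10 were lower and 1 was higher in every pair of plates (median -0.91, from -0.91 to -0.52, percentile 0.04). Nhlh1, a basic helix-loop-helix factor of cells leaving the cycle, was at -1.76 and was detected in 52.9% of E15 cells and 1.85% of P2 cells. Mfap4 was at -1.98, Gadd45g at -1.49 and Btg2 at -1.35. Eomes, the transcription factor that defines these progenitors, went the other way, at 0.68 (0.24 to 1.14). The percentile of this list was 5.51 without P2 plate 1 and 13.81 in cells matched on detected genes.

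Of 9 measured radial glia genes, 4 were higher and 1 was lower in every pair of plates (median 0.20, from -0.18 to 0.54, percentile 99.97). Pax6 was at 0.90, Ptprz1 at 0.79 and Sox2 at 0.57, whereas the intermediate filament gene Vim was at -0.81. The list median turned to -0.17 without E15 set A (percentile 81.1) and the percentile was 97.21 without P2 plate 2. The median was -0.051 without cells with few detected genes, -0.021 in cells with Neurod6 detected and -0.016 without cells with many G2/M genes. Pan-neuronal genes had a median of -0.75 (-1.06 to -0.43, percentile 0.21), with 9 of 15 lower and 3 higher in every pair. The adhesion molecule L1cam was at -1.82, with detection in 57.9% and 3.70% of cells, Cntn2 at -1.47, Elavl4 at -1.43 and Map2 at -1.32. Without E15 set B the pan-neuronal percentile was 9.82, and it was 8.34 in cells matched on the mean level of this list.

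Regulators of pallial regional identity had a median of -0.75 (-0.96 to -0.17, percentile 0.01), with 5 of 10 lower and 2 higher in every pair. Nr2f1 was at -1.33, Emx1 at -1.05 and Nr2f2 at -0.99. The percentile was 6.48 without E15 set B.

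**Figure D3:**
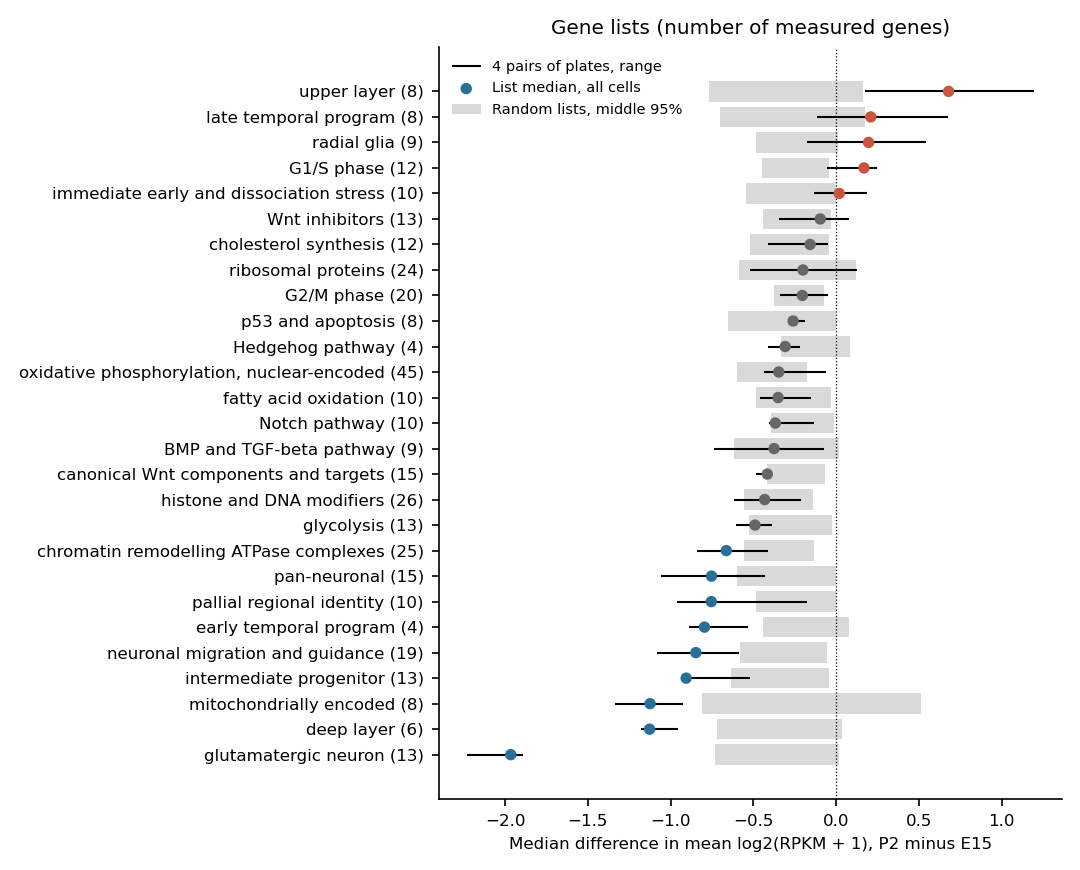
Median difference in mean log2(RPKM + 1), P2 minus E15, over the measured members of each of the 27 lists with a percentile. Dots are all cells (red above and blue below the middle 95% of random lists, grey inside it), black lines the range over the 4 pairs of plates and grey bars the middle 95% of 10000 random lists; the glutamatergic neuron list lies lowest at -1.97 and the upper layer list highest at 0.68.

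Genes of neuronal migration and guidance were lower as a group, with 12 of 19 measured members lower and 4 higher in every pair of plates (median -0.85, from -1.08 to -0.58, percentile 0.03). Of the 19 genes, 2 are also in the glutamatergic list. Members went both ways: Nrp1, Sema6d and the ephrin receptor Epha4 (-2.37, detected in 80.2% and 37.0% of cells) were lower and Sema3c higher. The early temporal program, genes expressed by young cortical progenitors, was lower in all 4 measured members (median -0.80, from -0.89 to -0.53, percentile 0). Its RNA-binding proteins Igf2bp3, Igf2bp1 and Igf2bp2 were at -0.93, -0.86 and -0.73. Igf2bp3 was detected in 40.5% of E15 cells and 6.48% of P2 cells. Without a filter on low values its percentile was 2.89. In the late temporal program 3 of 8 genes were higher and 1 was lower in every pair (median 0.21, from -0.11 to 0.67, percentile 98.2). Besides Zbtb20, Luzp2 was at 0.69 and Nfix at 0.48, while Nfia was at -0.36 (-0.78 to 0.06). The late temporal median turned to -0.18 without E15 set A (percentile 80.5), and its percentile was 89.8 without P2 plate 2. In cells matched on detected genes, with Neurod6 detected, or without many G2/M genes it was 94.09, 96.28 and 94.01.

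Genes of canonical Wnt signalling were mostly lower at P2, by a median that lay just inside the range of random lists. Of 15 measured members, 10 were lower and 1 was higher in every pair of plates (median -0.42, from -0.49 to -0.40, percentile 2.73, which ran from 0.09 to 7.07 over the settings). Ctnnb1, which encodes beta-catenin, was at -2.27 (-2.79 to -1.75) and was detected in 82.6% of E15 cells and 42.6% of P2 cells, and its exons overlap those of Ulk4. The receptor gene Fzd1 was at -1.84, detected in 40.5% of E15 cells and listed below 1 RPKM in all P2 cells. Mycn was at -1.19 and Fzd3 at -0.80. Wnt inhibitors had a median of -0.10 (-0.35 to 0.08, percentile 90.8), with 4 of 13 lower and 3 higher in every pair. Apc2 was at -1.06 and Sfrp1 at -0.76, while Gsk3b and Znrf3 were each at 0.54. That median was 0.11 with the log2 of the mean RPKM.

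Subunits of chromatin remodelling ATPase complexes were lower, with 17 of 25 measured genes lower and 2 higher in every pair of plates (median -0.66, from -0.84 to -0.41, percentile 0.34). Chd3 was at -1.47, Actl6a at -1.39 and Smarce1 at -1.22, whereas the ATPase gene Smarca2 was at 1.28. The percentile was 4.22 without E15 set B, 3.58 without P2 plate 1, 3.135 with the log2 of the mean RPKM, 3.25 in cells matched on detected genes and 6.16 without cells above 20% mitochondrially encoded RPKM. Histone and DNA modifiers had 18 of 26 members lower and 2 higher in every pair, and their median of -0.43 (-0.62 to -0.21, percentile 18.9) was inside the range of random lists. Hdac2, a histone deacetylase, was at -2.17, with detection in 76.0% and 35.2% of cells. Kdm1a was at -1.33 and Ezh2, the methyltransferase of Polycomb repression, at -1.32.

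All 8 measured mitochondrially encoded genes were lower at P2 in every pair of plates (median -1.12, from -1.33 to -0.93, percentile 0.18). mt-Nd5 was at -1.79, mt-Nd4 at -1.49, mt-Nd6 at -1.47 and mt-Nd3 at -1.38. More than 20% of the RPKM total came from mitochondrially encoded genes in 22 E15 cells and 2 P2 cells. Without these cells the list's median was -0.87 and its percentile 23.7, inside the range of random lists. The percentile was 3.79 without cells with few detected genes. The 45 nuclear-encoded genes of oxidative phosphorylation had a median of -0.35 (-0.43 to -0.06, percentile 61.1), with 18 lower and 3 higher in every pair. Among them Ndufv1 was at -1.01 and Cox5b at 1.02. Their median turned to 0.31 in cells matched on detected genes, to 0.06 in cells matched on the pan-neuronal level (percentile 98.8) and to 0.12 with the log2 of the mean RPKM, and was -0.76 without cells above 20% mitochondrially encoded RPKM. Glycolysis had 9 of 13 genes lower and 0 higher in every pair (median -0.49, from -0.61 to -0.39, percentile 4.40). Pkm, which encodes pyruvate kinase, was at -1.96 and Ldha at -0.95. The glycolysis percentile ran from 0.73 without E15 set B to 34.4 without E15 set A. It was 2.375 without the cells above 20% (median -0.74), and the median was -0.14 in cells matched on detected genes.

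Fatty acid oxidation had a median of -0.35 (-0.46 to -0.15, percentile 19.6), with 5 of 10 genes lower and 1 higher in every pair of plates; Cpt1c was at -0.72 and Hadha at -0.66. Cholesterol synthesis had a median of -0.16 (-0.41 to -0.05, percentile 83.8), with 5 of 12 lower and 0 higher; Fdft1, squalene synthase, was at -1.17 and Hmgcs1 at -0.57. Fatty acid oxidation turned to 0.08 with the log2 of the mean RPKM and cholesterol synthesis to 0.19 in cells matched on detected genes. Without cells above 20% mitochondrially encoded RPKM the cholesterol median was -0.35.

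The Notch pathway had a median of -0.37 (-0.40 to -0.13, percentile 4.48), with 6 of 10 genes lower and 1 higher in every pair of plates. The ligand gene Dll1 was at -0.92, with detection in 27.3% and 1.85% of cells, and the target Hey1 at -0.74, with 20.7% and 0.93%. The Notch percentile ran from 0.34 with median ratio scaling to 88.0 with no filter on low values (median -0.0061), and it was 2.36 without P2 plate 2. All 4 measured Hedgehog genes were lower (median -0.31, from -0.41 to -0.22, percentile 5.24), led by the co-receptor Boc at -0.54. The Hedgehog percentile ran from 0.90 on the TPM scale to 35.8 without E15 set B, and it was 1.33 without E15 set A. The BMP and TGF-beta pathway had a median of -0.38 (-0.74 to -0.07, percentile 29.5), with 5 of 9 lower and 1 higher in every pair. Its members went both ways, with Tgfbr1 at -1.07 and Id2 at 1.00 (-0.11 to 2.13).

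Immediate early and dissociation stress genes had a median of 0.02 (-0.14 to 0.18, percentile 98.1), with 3 of 10 higher and 2 lower in every pair of plates. Egr1 and Jun (0.58) were higher and Hsp90aa1 was at -0.86. The percentile was 79.7 without P2 plate 2 (median -0.16) and 94.45 without E15 set B. It was 95.06 with the log2 of the mean RPKM, 96.61 in cells with Eomes detected (median -0.02) and 92.47 in cells matched on the pan-neuronal level. The median was -0.03 without cells with few detected genes and -0.08 without cells above 20% mitochondrially encoded RPKM. Genes of p53 and apoptosis had a median of -0.26 (-0.28 to -0.19, percentile 57.8), with 4 of 8 lower and 1 higher. Bcl2l1 was at 0.55 and Mdm2 at -0.44. Ribosomal protein genes had a median of -0.20 (-0.52 to 0.12, percentile 65.2), with 8 of 24 lower and 3 higher. In cells matched on detected genes the medians were 0.17 for p53 and apoptosis and 0.41 for ribosomal proteins, and the latter was 0.16 in cells matched on the pan-neuronal level. Without cells above 20% mitochondrially encoded RPKM they were -0.43 and -0.64.

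Cell cycle genes were detected in a minority of cells at both ages. At least 10 of the 20 G2/M genes were detected in 13 of 121 E15 cells (10.7%, exact 95% binomial interval 5.85 to 17.7) and 10 P2 cells (9.26%, 4.53 to 16.4); this limit was chosen after the values were seen. The direction turned at a limit of 5 genes, which 14.9% of E15 cells and 16.7% of P2 cells reached. Mki67, a marker of cycling cells, was detected in 21.5% of E15 cells (14.5 to 29.9) and 11.1% of P2 cells (5.87 to 18.6), and Top2a in 27.3% (19.6 to 36.1) and 25.9% (18.0 to 35.2). The Mki67 share was lower on both P2 plates (12.7% and 9.43%) than on both E15 plates (20.0% and 23.0%), and no test of these differences was made. The G2/M list had a median of -0.20 (-0.34 to -0.05, percentile 56.5), with 10 of 20 genes lower and 1 higher in every pair of plates. Its place among random lists was not stable over plates: the percentile was 1.13 without P2 plate 1 and 98.1 without P2 plate 2. In cells matched on detected genes the median was 0.62 (percentile 100). The same matching turned Mki67 from -0.41 to 0.27 and Top2a from -0.18 to 0.96. Matching can itself change the share of cycling cells. A cluster on variable genes (13 E15 and 7 P2 cells, Top2a among its top genes) had medians of 3513 and 2868 detected genes. The matched cells had medians of 2550.5 and 2358. How many cycling cells of each age were kept was not measured, so these turns decide nothing about the ages. The G1/S list had a median of 0.17 (-0.06 to 0.24, percentile 99.98), with 3 of 12 genes higher and 4 lower in every pair. Slbp was at 0.51, Mcm6 at 0.44 and Rrm1 at -0.38. Without E15 set B the G1/S median was -0.08 (percentile 88.8), and it was -0.05 in cells with Eomes detected (percentile 96.8) and -0.06 in cells matched on the pan-neuronal level (percentile 88.85).

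The share of cells with Neurog2 transcript was 30.6% at E15 (22.5 to 39.6) and 29.6% at P2 (21.2 to 39.2). Its direction turned with the detection limit, with 18.2% and 23.1% at 5 RPKM but 42.1% and 35.2% above 0. Neurog2 varied between plates, from 18.3% in E15 set A to 42.6% in E15 set B, and its difference of 0.27 turned to -0.11 without E15 set A. Eomes was detected in 63.6% of E15 cells (54.4 to 72.2) and 72.2% of P2 cells (62.8 to 80.4). Its share was 51.7% in E15 set A, 75.4% in E15 set B, 74.5% on P2 plate 1 and 69.8% on P2 plate 2, so without E15 set A it was higher at E15. Pax6 was detected in 22.3% (15.2 to 30.8) and 44.4% (34.9 to 54.3), and Sox2 in 3.31% (0.908 to 8.25) and 19.4% (12.5 to 28.2). Neurod1 was detected in 91.7% (85.3 to 96.0) and 51.9% (42.0 to 61.6), Neurod2 in 87.6% (80.4 to 92.9) and 40.7% (31.4 to 50.6), and Neurod6 in 97.5% (92.9 to 99.5) and 80.6% (71.8 to 87.5). Tbr1 was detected in 68.6% (59.5 to 76.7) and 52.8% (42.9 to 62.5), but at 5 RPKM its shares were 38.8% and 39.8%. These intervals are exact 95% binomial intervals and cover counting error only.

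**Figure D4:**
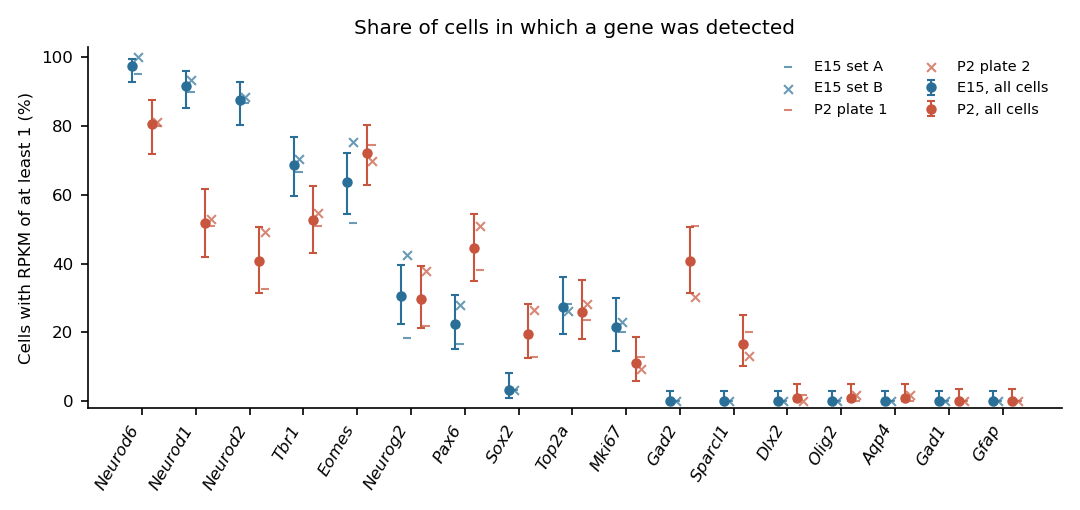
Percent of cells with each gene detected (RPKM of at least 1), by age; dots are all cells of an age with exact 95% binomial intervals, and dashes and crosses its plates. Neurod1 was in 91.7% of E15 and 51.9% of P2 cells, whereas Neurog2 was in 30.6% and 29.6%.

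Most markers of other cell types were rare. Gad1 was detected in 0 of 229 cells. With a floor of 3 cells, a count of 0 allows detection in up to 2.48% of E15 and 2.78% of P2 cells. The exact 95% intervals for a count of 0 are wider, up to 3.00% and 3.36%, and either bound limits cells with the transcript detected and not cells that express it. Gfap too reached 1 RPKM in 0 cells, and Dlx2, Olig2 and Aqp4 each in 1 P2 cell and 0 E15 cells. Gad2, which encodes a glutamate decarboxylase of GABAergic neurons, was detected in 44 P2 cells (40.7%, 31.4 to 50.6) and 0 of 121 E15 cells. The P2 share was 50.9% on plate 1 and 30.2% on plate 2, and the median level in detected cells was 17.3 RPKM. Gad2 lies on chromosome 2 from 22622205 to 22693874 on the plus strand, and its exons overlap no other annotated gene. It was the only measured member of the GABAergic list. The astrocyte list had 2 measured members, Sparcl1, detected in 0 E15 cells and 16.7% of P2 cells (10.2 to 25.1), and Slc1a2, in 1.65% and 10.2%. Lists of oligodendrocyte lineage, microglia, endothelial and mural, erythroid, Cajal-Retzius and ependymal cells had 0 measured members. No gene of these lists was detected in more than 6.61% of E15 cells (the share of Reln) or 2.78% of P2 cells (Calb2), and no microglial gene reached 1 RPKM in any cell. These 8 lists have no percentile.

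Clustering on 71 marker genes put 90.4% of the cells in a cluster where their own age led. Clusters also differed in detected genes: medians were 2975, 2666.5 and 2978.5 where E15 led and 2382, 1870 and 1937 where P2 led. In the P2-led clusters with 10 and 5 E15 cells, those cells had medians of 1202 and 1374. Age and the number of detected genes were thus not separated here. A cluster of 52 E15 cells and 0 P2 cells met the naming rule as neuron-like, with Nrp1, Neurod6, Neurod1 and Bcl11b among its top genes. The largest cluster, with 57 P2 and 5 E15 cells, had Sema3c, Fam84a, Spry2, Cdk6 and Pou3f2 among its top genes and met no naming rule. The other 4 clusters held 38 and 3, 14 and 2, 2 and 19, and 10 and 27 E15 and P2 cells, and were not named. No named class held at least 10 cells of each age, so the planned comparisons within a class were not made. None of these clusters was named as progenitors, so neurons were not compared with progenitors within an age. With E15 cells clustered alone, a cluster of 26 cells met the naming rule for intermediate progenitors, with Mfap4, Btg2 and Eomes among its top genes. No cluster there met it for neurons. Cluster sizes are not read as the composition of the tissue.

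**Figure D5:**
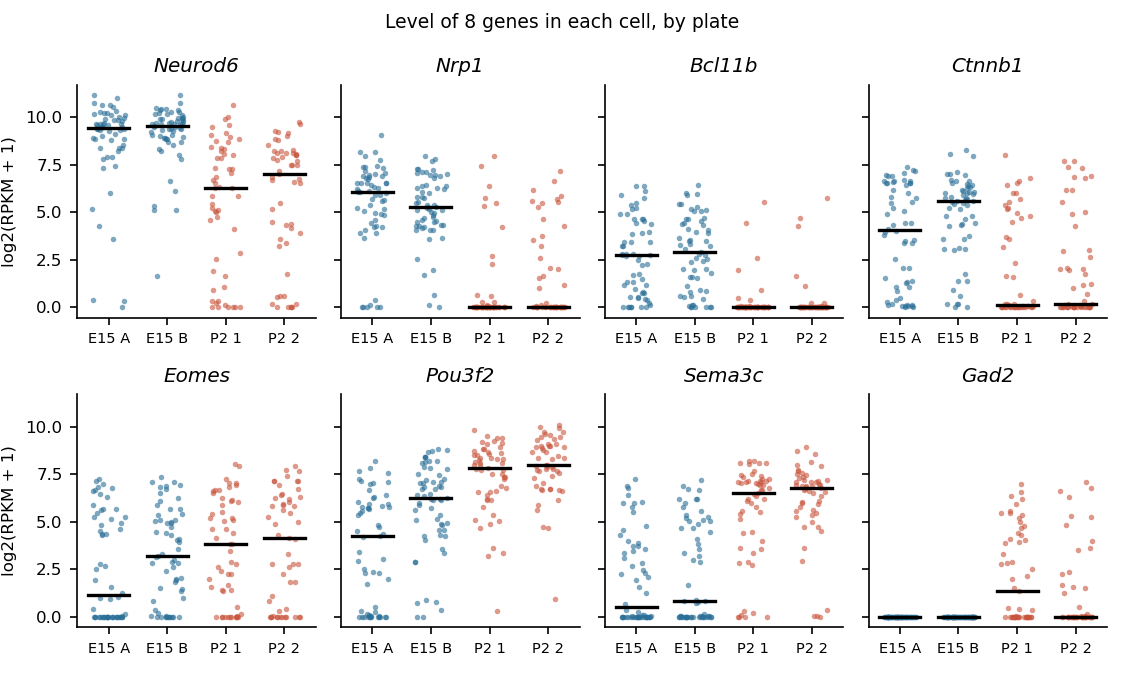
Level per cell, log2(RPKM + 1), of Neurod6, Nrp1, Bcl11b, Ctnnb1, Eomes, Pou3f2, Sema3c and Gad2 in the 4 plates; each point is a cell and each line the median of its plate. Nrp1 was detected in 91.7% of E15 cells and 27.8% of P2 cells, and Gad2 in 0 E15 cells and 40.7% of P2 cells.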

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

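Settings added after the data had been examined were those that kept the empty P2 column, took cells with Eomes or Neurod6 detected, left out cells with 10 or more G2/M genes or above 20% mitochondrially encoded RPKM, matched cells on the pan-neuronal level or on assigned reads, or counted 5 G2/M genes; the others were fixed before. No paired analysis was possible because each age is 1 sample with no animal named, and numbers in the cell titles pair no cells. The other settings laid out for comparisons within a class and of neurons with progenitors were not run, since those comparisons were not made. The 24 genes with the largest differences kept their sign in all 432 values over 18 settings. The naming rule asked for the same sign in every pair of plates, so the signs without 1 plate were fixed by it. Other settings largely reuse the same cells, so this count is not independent support. Neurod1 kept the smallest share of its difference, 51.7%. Of 14 lists outside the range of random lists, 3 (glutamatergic neuron, upper layer, and migration and guidance) stayed outside in all 18 settings (12 planned, 6 added). The 14 lists kept their side in 220 of 252 values, and the 13 lists inside the range came outside it in 21 of 234.

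With the log2 of the mean, percentiles were 3.135 for chromatin remodelling and 95.06 for immediate early genes. With no filter on low values, deep layer was at 26.97 and early temporal at 2.89. Without cells with few detected genes, radial glia were at 97.04 (median -0.051), mitochondrially encoded genes at 3.79, and the immediate early median was -0.031. Matched on detected genes, intermediate progenitor was at 13.81, chromatin remodelling at 3.25 and late temporal at 94.09. In Eomes-detected cells, G1/S was at 96.775 (median -0.054) and immediate early at 96.61 (median -0.019). In Neurod6-detected cells, radial glia were at 95.145 (median -0.021) and late temporal at 96.28. Without cells with many G2/M genes, radial glia were at 95.73 (median -0.016) and late temporal at 94.01. Matched on the pan-neuronal level, pan-neuronal was at 8.34, G1/S at 88.85 (median -0.063) and immediate early at 92.47. Without cells above 20% mitochondrially encoded RPKM, those genes were at 23.69, chromatin remodelling at 6.16, and the immediate early median was -0.080.

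Leaving out 1 plate at a time gave percentiles from 88.795 to 100 for G1/S (median -0.077 to 0.21), 79.71 to 99.26 for immediate early (-0.16 to 0.10), 80.54 to 99.93 for late temporal (-0.18 to 0.61) and 81.11 to 100 for radial glia (-0.17 to 0.47). They ran from 0.09 to 4.22 for chromatin remodelling, 0.01 to 5.51 for intermediate progenitor, 0.03 to 6.48 for pallial identity and 0.12 to 9.82 for pan-neuronal. The difference in detected genes was -1082.5 at RPKM above 0 and -559.5 at 5 RPKM, where by construction more and fewer genes count. The difference in the share of cells with 5 G2/M genes was 1.79 points, higher at P2, where the share with 10 genes was lower, and variable genes put 95.2% of cells in a cluster of their own age. For the other values the cause was not tested. Depth limits rare transcripts: a transcript not detected in a cell is not shown to be absent from it, and how many cells this concerns was not measured. Log2 differences of genes at 0 in many cells move with the pseudocount, which took the median over measured genes to -0.51 at 0.1.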

Other observations

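The tests on cells with a high mitochondrial share, on GABAergic neurons, on gene models and on cells matched by pan-neuronal level were chosen after the results were seen; the other tests were chosen before their own results were seen, though some, such as matching on assigned reads, after other values had been examined. Transcripts that depend on the sex of the animals differed between plates. Xist was detected in 25 of 60 cells of E15 set A, 26 of 61 of set B, 0 of 55 of P2 plate 1 and 10 of 53 of P2 plate 2. Any of 4 Y-linked genes was detected in 17, 15, 42 and 24 cells of the same plates. Both were detected in 7 of 229 cells. Xist was rarer and Y-linked genes more frequent on both P2 plates than on both E15 plates, so the sex of the animals was not separated from age.

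P2 cells had fewer detected genes than E15 cells, with a difference of medians of -842. In 91 pairs of cells matched on assigned reads the median paired difference was -775. Among these matched cells, without regard to the pairing, the difference of plate medians lay between -661.5 and -1046.5 over the pairs of plates. These values argue against lower read depth as the whole cause. Cells over 20% mitochondrial made up 18.2% of E15 and 1.85% of P2 cells, which argues against more cells of that kind at P2. Without them the difference was -955 (-680 to -1161). That value adds no support, since the filter took mainly E15 cells and raised the E15 median from 2867 to 2999. Loss of quality that leaves the mitochondrial share low stays open: leaving out cells under 50% of the median of their age gave -912, but that filter acts on the outcome itself and decides nothing. A lower RNA content or a less diverse transcriptome of P2 cells may remain, as a hypothesis not tested here. Age, region, sex and capture run were not separated.

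Gad2 was detected in 44 P2 cells and 0 E15 cells, though the sort for Neurog2-driven tdTomato should remove GABAergic neurons. Another gene of the 13-gene GABAergic list was detected in 15.9% of the 44 (7 cells), and Gad1 in 0 cells. This rarity of other GABAergic genes argues against GABAergic neurons as the main source. Of the 13 genes, 1, Sp8, is also a pallial gene. Neurod6 or Eomes was detected in 90.9% of the 44. Over all P2 cells Neurod6 was detected in 80.6% and Eomes in 72.2%, so the 90.9% does not set the 44 cells apart. The highest Gad2 value was 10.3 times the median of detected cells on one P2 plate and 6.43 times on the other. Both are far below the 100 times set in advance for carry-over from a very strong cell. This covers only donors among the P2 cells compared, and reads from any other source were not tested. Gad2 had a value above 0 in 0 E15 cells and 48.1% of P2 cells, and Sparcl1 in 0 and 25.9%. The ages are in separate tables, and whether Gad2 was counted alike in both was not tested. Gad2 transcript in cells of the glutamatergic lineage may be a property of the P2 cells, which is a hypothesis found and tested on the same data.

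The glutamatergic neuron list was lower at P2. Without Neurod6 its median was -1.92 in cells with Neurod6 detected and -1.92 in all cells, but that selection keeps 97.5% of E15 and 80.6% of P2 cells and is weak. In 88 pairs matched on the pan-neuronal level the median of the whole glutamatergic list was -1.96 (-1.61 to -2.28 over the pairs of plates). The match was on the mean over the pan-neuronal list and did not equalise its genes. The pan-neuronal median was at most -0.43 in every setting, and its percentile in the matched cells was 8.34. These pairs therefore do not settle whether fewer neurons at P2 are the cause. In cells paired on detected genes the median was -1.81 (-1.65 to -2.02), 91.9% of the value over all cells, and 100% of the 13 genes had at least 90% of their low values within 0.05 of whole reads with 1 gene length in both tables, which argues against fewer detected genes and against different gene models. A difference in neuron type or maturity between the ages stays open as a hypothesis, and age, region and sex were not separated.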
